A study of Mus musculus with 12 samples.

How the data were processed

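Chromatin immunoprecipitation followed by sequencing was performed on MLL-AF9-transformed mouse progenitors with antibodies to Jmjd2a, Jmjd2c, trimethylated lysine 9 and trimethylated lysine 36 of histone H3, in untreated cells and in cells treated with 4-hydroxytamoxifen. The groups were taken from the sample titles. Jmjd2a and Jmjd2c have 1 library per condition and each histone mark has 2. Per the submitters' processing notes, Bowtie 0.12.7, SAMtools and bedtools 2.25.0 were used and the genome build was mm10. The peak caller, its threshold, its control library and the libraries that entered each peak list are not given in the sources used here, nor is it stated whether libraries were pooled.

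The authors deposited positions in bp of called regions for Jmjd2a and for Jmjd2c, with the RefSeq features under each peak, the nearest start site and a distance in bp, per the file headers. They also deposited a table of windows reaching 1 kb to each side of start sites bound by both proteins, per the first line of that table. How binding of a window was decided is not given in the sources used here. None of these columns holds a height, a score, a p-value or a value per library. A library's depth therefore cannot be read from them, and neither OHT against control nor either histone mark was tested. Calls from a shallow library miss weak sites, so the number, width and share of peaks depend on depths and thresholds that are unknown.

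Positions were read as starting from 0 with an open end, from the 1 bp length of the start-site entries, and are printed counting from 1. The deposited distance is 0 where a peak covers a start site and otherwise 1 bp more than the gap. The 3 Jmjd2a peaks outside the numbered, X and Y chromosomes have no start site named and were counted as lying near none. A peak within 1000 bp of a start site was called near, and a peak more than 10000 bp away distal. A gene was called occupied when a start site named for it in the files lay within 1000 bp of a peak. Of 17007 RefSeq accessions in the files, 16875 were matched to genes of a RefSeq table on assembly GRCm38.p6, the same primary assembly as mm10, and 12429 start sites were used. The background was the 26219 genes with a curated RefSeq transcript on chromosomes 1 to 19, X and Y.

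Peaks were called shared when they overlapped by at least 1 bp. Their number was set against 1000 random placements of the other list that kept chromosome and width. Placement among start sites was replaced by the gene-level test, because the gene table used gives no strand. Gene sets and lists were tested with two-sided Fisher's exact tests, adjusted by Benjamini-Hochberg over 63 tests (21 lists for Jmjd2a, Jmjd2c and both) at a threshold of 0.05. Lists defined by a name pattern also took genes whose older symbols match. Among others, this adds Patz1 and Zbtb14 to the zinc finger genes and Mrpl23 to the ribosomal proteins. The spliceosome list gains Srek1ip1, Akap17b, Clasrp, Pnisr, Scaf4, Scaf11, Sfswap and Sugp2. The proteasome list gains Nob1, and the respiratory chain list gains Emc8, Dmac2 and Dmac2l. Psme3ip1 and Psmc3ip match the proteasome pattern by their present symbols. All counts include these genes. Median widths were compared with permutation tests of 100000 resamples. Shares carry exact (Clopper-Pearson) 95% binomial intervals. On simulated data the overlap step found 100% of planted partners, which were given to a random part of 8974 peaks. Each partner was a copy of its peak shifted by less than the narrowest peak width, so overlap was certain and only the code was checked. The list test, over 26219 genes, called 96.8% of planted lists of 40 genes with a share of 60% against 27%, and 1.25% of lists with no planted difference. Genes were drawn independently at a single base share, so these rates need not hold for real lists. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.

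The gene lists, the tests of the peak and gene sets, part of the alternatives and the rule for named genes were chosen before the data were examined. That rule takes Kdm4a, Kdm4b, Kdm4c, Kdm4d, Il3ra, Csf2rb, Hoxa9, Meis1 and Myc, up to 4 occupied members of each list with the strongest peak, those with both proteins coming before the others, the 10 strongest peaks of each protein near start sites and the 5 strongest distal ones. The peak lists give no score, so peak width took its place in this rule, in the comparison of shared with unshared peaks and in the stricter threshold, which kept the wider 50% of each list. Width is not a measure of signal. Some genes that the rule names, or that lie in a region described, are not reported here. Other alternatives were windows of 500 and 5000 bp, an overlap of at least 50% of the shorter peak or a distance within 1000 bp, and other backgrounds. For the overlap of the gene sets these were all protein-coding genes, and protein-coding genes without predicted genes (Gm and Rik names) and olfactory and vomeronasal receptor families. For the gene lists and the X-linked genes only the latter background was run. The width threshold, peaks set to 500 bp around their middle, added gene ends and the removal of X-linked genes were alternatives chosen after seeing the data. The comparisons of X-linked with autosomal start sites and of Jmjd2a among Jmjd2c-occupied genes were added after the data were seen.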

Results

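The study asked which genes the histone demethylases Jmjd2a (Kdm4a) and Jmjd2c (Kdm4c) occupy in mouse leukaemic granulocyte-macrophage progenitors transformed by the MLL-AF9 fusion. These enzymes remove methyl groups from lysine 9 and lysine 36 of histone H3. The cells carry floxed alleles of Jmjd2a, Jmjd2b and Jmjd2c and a tamoxifen-activated Cre recombinase, and were grown in medium with 20% serum and 10 ng/ml interleukin-3. Chromatin from untreated cells and from cells given 500 nM 4-hydroxytamoxifen (OHT) for 96 h was immunoprecipitated and sequenced. The 12 libraries fall into 8 groups. Jmjd2a and Jmjd2c have 1 untreated and 1 OHT library each, and trimethylated lysine 9 and trimethylated lysine 36 have 2 libraries per condition. The deposited tables examined here hold a list of Jmjd2a peaks, a list of Jmjd2c peaks and a table of transcription start sites bound by both proteins. They carry no value per library, so sequencing depth is unknown, and the OHT effect and the histone marks were not analysed here. No replicate check exists for either peak list. Intervals and p-values below cover counting error over peaks or genes, which are not replicates.

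Il3ra, which encodes the alpha subunit of the interleukin-3 receptor, lay under a peak of each protein. The Jmjd2a peak spanned 1838 bp (chromosome 14, 14345539 to 14347376) and the Jmjd2c peak 1358 bp (14345744 to 14347101), and both covered the start site of the gene (14345912 to 14355493, plus strand, mm10). Across the genome Jmjd2a had 8977 peaks with a median width of 706 bp (interquartile range 484 to 1002), covering 7.05 Mb. Jmjd2c had 10521 peaks with a median width of 1302 bp (interquartile range 937 to 1679), covering 14.1 Mb.

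**Figure D1:**
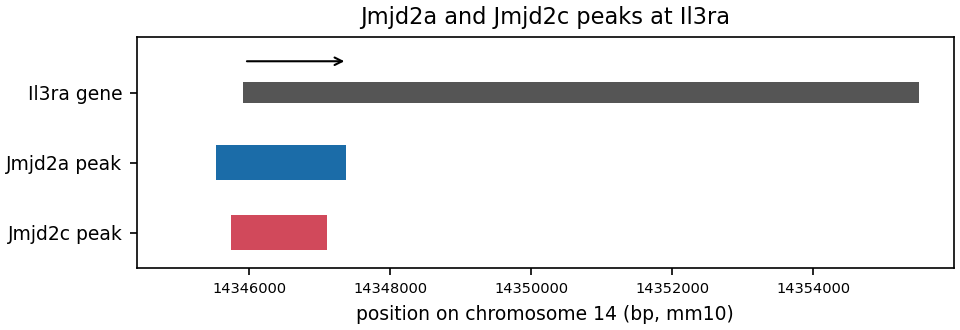
Map of Il3ra on chromosome 14 (mm10, position in bp), with the gene (grey, arrow in the direction of transcription), the Jmjd2a peak (blue) and the Jmjd2c peak (red) drawn to scale. The Jmjd2a peak spans 1838 bp and the Jmjd2c peak 1358 bp, and both cover the start of the gene at 14345912.

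Peaks of both proteins were concentrated at gene starts, those in the Jmjd2c list more than those in the Jmjd2a list. A start site lay within 1000 bp of 6908 Jmjd2a peaks (77.0%, exact 95% binomial interval 76.1 to 77.8) and of 9053 Jmjd2c peaks (86.0%, 85.4 to 86.7). The difference between the lists gave an odds ratio of 1.85 (Fisher's exact test, two-sided p = 1.85e-60). Peaks that covered a start site made up 51.3% of the Jmjd2a list and 78.3% of the Jmjd2c list, and those touching an annotated 5′ untranslated region made up 63.8% and 82.6%. Distances run from the peak edge, and Jmjd2c peaks were wider (median 1302 against 706 bp). These shares therefore depend on width, and on the unknown depth and threshold of each list. The widest Jmjd2a peaks near a start site lay at Jag1, a Notch ligand (3450 bp), at the transcription factor gene Sox4 (3339 bp) and at Foxc1 (2744 bp), followed by Maf and Adra2a. All of these overlapped Jmjd2c, as did the promoters shared by Pfkfb2 and Yod1, Extl2 and Slc30a7, Pxmp2 and Pole, Dclre1a and Nhlrc2, and Myd88 and Acaa1a. The widest Jmjd2c peaks near a start site lay at Gnas (5046 bp), Gse1 (4721 bp), Anp32a (4622 bp), Spry2 (4590 bp), 1190002F15Rik (4560 bp) and Mxi1 (4514 bp). Those at Gnas, Gse1, Spry2, 1190002F15Rik, Tnrc18 and the cell-cycle kinase gene Cdk6 (4309 bp) had no overlapping Jmjd2a peak, whereas those at Anp32a, Mxi1, Ap3m2 and the shared promoter of Gpr108 and Trip10 did.

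Peaks far from start sites were fewer. A distance of over 10 kb to the nearest start site was found for 1381 Jmjd2a peaks (15.4%, 14.6 to 16.1) and 905 Jmjd2c peaks (8.60%, 8.07 to 9.15; odds ratio 0.518, Fisher's exact test, two-sided p = 1.34e-48). Of these distal peaks, 954 in the Jmjd2a list and 636 in the Jmjd2c list overlapped no RefSeq feature. Their median widths were 525 bp for Jmjd2a and 823 bp for Jmjd2c. The widest distal Jmjd2a peak (1973 bp; chromosome 5, 33819679 to 33821651) lay 21461 bp from the start of Whsc1, a lysine 36 methyltransferase gene also called Nsd2. Others lay nearest to Pcmtd1, Vgll4 and Foxn3, the last over an intron and 5′ untranslated region of the gene. The widest distal Jmjd2c peak (3656 bp; chromosome 6, 99520067 to 99523722) was intergenic and 84722 bp from Foxp1, and further wide ones lay nearest to Mir6417, Gltscr1l, Nlrp4f and Chd9, the last over an intron and 5′ untranslated region.

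The next comparison asked how far the Jmjd2a and Jmjd2c sites coincide. Il3ra, Kdm4c, Kdm4d and Myc carried both proteins near a start site, Kdm4a, Kdm4b and Meis1 carried Jmjd2c only, and Csf2rb, which encodes the common beta subunit of the interleukin-3 receptor, and Hoxa9 carried neither. Of the Jmjd2a peaks, 6651 (74.1%, 73.2 to 75) overlapped a Jmjd2c peak by at least 1 bp, and 6167 Jmjd2c peaks (58.6%, 57.7 to 59.6) overlapped a Jmjd2a peak. Random placement on the same chromosomes gave means of 82.8 and 82.0 shared peaks and maxima of 111 and 110 in 1000 placements, so the observed numbers were 80.3 and 75.2 times those means (permutation p over placements = 0.001, the smallest that 1000 placements can give). The placements did not keep the distance to start sites, where both lists concentrate. Within 1000 bp of a start site 86.9% of Jmjd2a peaks (86.1 to 87.7) and 61.6% of Jmjd2c peaks (60.6 to 62.6) were shared, against 28.1% (25.7 to 30.5) and 40.6% (37.3 to 43.8) of those over 10 kb away.

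Shared peaks were wider than unshared ones in both lists. The medians were 781 against 525 bp for Jmjd2a and 1394 against 1129 bp for Jmjd2c (permutation test of the medians, two-sided p = 1e-05 for each, the smallest that 100000 resamples can give). Near start sites alone they were 791 against 615 bp and 1425 against 1244 bp (permutation p = 1e-05 for each). Width and overlap are not independent measures, and the lists give no height or score.

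At the 6940 start-site windows of the authors' deposited table, all of which overlapped a peak of each list, coverage peaked just inside the gene. Jmjd2c peaks covered the start site itself in 94.1% of windows, and Jmjd2a peaks in 67.2%. Coverage reached 95.9% at 175 bp downstream for Jmjd2c and 77.5% at 200 bp downstream for Jmjd2a. At 500 bp upstream it was 64.5% and 40.4%, and at 500 bp downstream 88.3% and 54.8%.

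**Figure D2:**
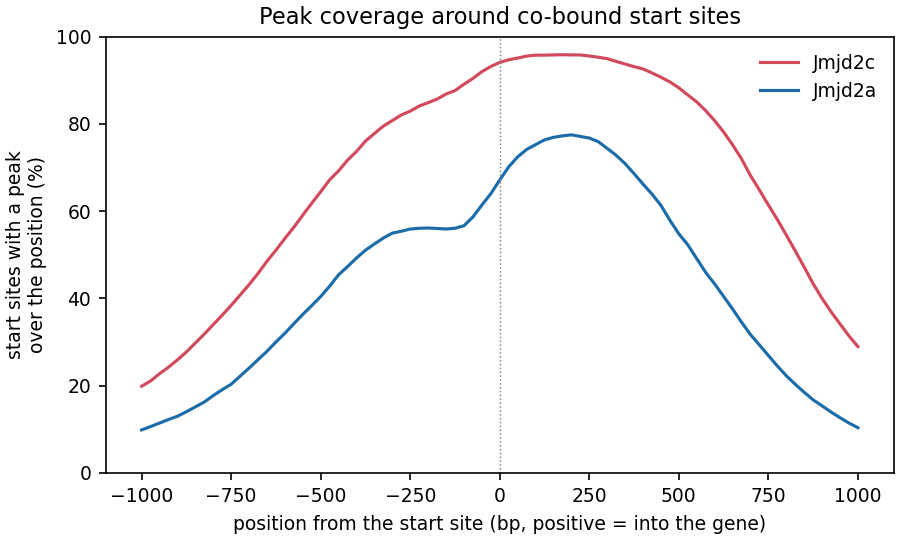
Share of the 6940 start-site windows in the authors' deposited table with a Jmjd2c peak (red) or a Jmjd2a peak (blue) over each position, from 1000 bp upstream to 1000 bp downstream of the start site in the direction of transcription. Both lines are highest inside the gene, at 95.9% for Jmjd2c and 77.5% for Jmjd2a.

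At the level of genes, Jmjd2a occupied the start of 7176 genes (27.4% of 26219 RefSeq genes) and Jmjd2c that of 9927 (37.9%). Both occupied 6422 genes, among them Il3ra, Myc, Kit and Kdm4c, while 754 genes had Jmjd2a alone and 3505 had Jmjd2c alone. Independent sets of these sizes would share 2717 genes, so the observed number was 2.36 times that (odds ratio 37.8, Fisher's exact test, two-sided p below 1e-300). Among protein-coding genes without predicted genes and receptor families the ratio was 1.80, over 18479 genes. Neither background was matched on promoter type. The test therefore cannot tell joint targeting from a preference of both proteins for the same class of promoters. The specificity of the antibodies could not be checked from peak positions, so signal common to both antibodies is not excluded either. Jmjd2c occupied 89.5% of the Jmjd2a genes, and Jmjd2a occupied 64.7% of the Jmjd2c genes. The start sites used were those of the authors' table of co-bound sites and the nearest one of each peak. A further gene near a peak of a single protein could thus be missed, which can raise these shares and the odds ratio. Counted over peaks within 1000 bp of a start site, the shared parts were 86.9% for Jmjd2a and 61.6% for Jmjd2c. The authors' deposited table holds 6418 distinct entries for gene names, a few of which join several names, and its windows matched 6422 RefSeq genes by accession or name. Of the matched genes 6412 were bound by both in the peak lists, and 10 genes bound by both were not in the authors' deposited table. The start sites of that table were among those used here, so this match is not an independent check.

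The genes of the KDM4 family, to which Jmjd2a and Jmjd2c belong, all had Jmjd2c at a start site (4 of 4). Kdm4c had a Jmjd2a peak of 345 bp (chromosome 4, 74251332 to 74251676) beside a Jmjd2c peak of 2087 bp, and Kdm4d had peaks of 901 and 1716 bp (chromosome 9, 14499600 to 14500500 for Jmjd2a). Jmjd2c alone was found at Kdm4a, as a peak of 1465 bp (chromosome 4, 118179187 to 118180651), and at Kdm4b, as a peak of 585 bp (chromosome 17, 56325942 to 56326526). The share of the family with Jmjd2c lay above that of other genes (adjusted exact p = 0.0275), but not against protein-coding genes without predicted genes and receptor families (adjusted exact p = 0.089) or with the wider 50% of peaks (adjusted exact p = 0.0594). Each list below was compared with all other genes by a two-sided Fisher's exact test, adjusted by Benjamini-Hochberg over 63 tests of 21 lists.

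Enzymes that write, erase or read methylation of lysine 9 and lysine 36 were occupied often, Jmjd2a being at 20 of 32 (62.5%, 43.7 to 78.9; adjusted exact p = 6.26e-05) and Jmjd2c at 29 of 32 (90.6%, 75 to 98.0; adjusted exact p = 3.05e-09). Of all Jmjd2a genes 89.5% also had Jmjd2c, and all 20 genes here had both proteins. They include Suv39h2, a lysine 9 methyltransferase (peaks of 1856 bp for Jmjd2a and 2473 bp for Jmjd2c), the heterochromatin corepressor gene Trim28 (2123 and 1832 bp), the demethylase gene Kdm7a (1434 and 2383 bp) and the histone chaperone gene Daxx (885 and 2258 bp). Other histone demethylase genes and relatives carried Jmjd2c at 17 of 18 (94.4%, 72.7 to 99.9; adjusted exact p = 2.12e-06). Jmjd2a was at 8 of the 18 (44.4%), Kdm8, Phf2, Jmjd6 and Hspbap1 among them, which did not pass the test (adjusted exact p = 0.139) but did so with a 5000 bp window (55.6% against 28.7% of other genes, adjusted exact p = 0.023). The share with both proteins, 44.4% against 24.5%, did not pass either (adjusted exact p = 0.0709), but did so with that window (55.6%, adjusted exact p = 0.0155) and without X-linked genes (50%, adjusted exact p = 0.0471).

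Interleukin-3 receptor and JAK-STAT5 signalling genes, the pathway of the cytokine in the growth medium, had Jmjd2c at 24 of 33 start sites (72.7%, 54.5 to 86.7; adjusted exact p = 0.000149) and Jmjd2a at 16 of 33 (48.5%, 30.8 to 66.5; adjusted exact p = 0.0144). Of all Jmjd2a genes 89.5% also had Jmjd2c, and all 16 genes here carried both proteins. Among these genes the widest peaks, at Akt1 (745 bp for Jmjd2a, 2899 bp for Jmjd2c), Grb2 (526 and 2667 bp), Gab2 (625 and 2080 bp) and Il3ra, belong to the kinase, the adaptors and the receptor of this pathway. Myc, a target of the pathway, had peaks of 432 and 1451 bp (chromosome 15, 61984853 to 61985284 for Jmjd2a). Against protein-coding genes without predicted genes and receptor families the Jmjd2c call held (adjusted exact p = 0.0144), and the Jmjd2a call did not (adjusted exact p = 0.204), nor with the wider 50% of peaks (adjusted exact p = 0.827). The share with both proteins passed against all other genes (adjusted exact p = 0.00533). It did not pass against that protein-coding background (adjusted exact p = 0.089) or with the wider peaks (adjusted exact p = 0.614).

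Target genes of MLL fusions showed Jmjd2c at 30 of 40 start sites (75%, 58.8 to 87.3; adjusted exact p = 7.92e-06) and Jmjd2a at 11 of 40 (27.5%, 14.6 to 43.9; adjusted exact p = 1), the latter against 27.4% of other genes. Both proteins were at Sox4, Pbx3, Cpeb2 and the cell-cycle inhibitor gene Cdkn1b, with Jmjd2a peaks of 3339, 1675, 1500 and 558 bp. Meis1, a homeobox gene active in MLL leukaemia, had a Jmjd2c peak 143 bp from its start (chromosome 11, 19019112 to 19020376), and its nearest Jmjd2a peak was 7258 bp away. Haematopoietic progenitor genes were not separable from other genes for Jmjd2c (14 of 28, adjusted exact p = 0.287) or Jmjd2a (7 of 28, adjusted exact p = 1). Kit, Bmi1, Egr1 and Sox4 of that list had both proteins, the peaks at the stem cell factor receptor gene Kit spanning 1261 and 1727 bp.

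Genes of DNA replication, DNA repair, splicing, protein degradation and respiration were occupied by each protein more often than other genes, as were zinc finger genes. The splicing, protein degradation, respiration and zinc finger lists include genes matched by older symbols. Jmjd2c lay at 39 of 42 DNA replication and cell-cycle genes (92.9%, adjusted exact p = 4.75e-13), 26 of 28 DNA damage response genes (92.9%, adjusted exact p = 6.37e-09), 50 of 55 spliceosome genes (90.9%, adjusted exact p = 1.49e-15), 47 of 52 proteasome genes (90.4%, adjusted exact p = 1.9e-14) and 87 of 98 respiratory chain genes (88.8%, adjusted exact p = 6.7e-25). Jmjd2a lay at 28 (66.7%, adjusted exact p = 4.14e-07), 20 (71.4%, adjusted exact p = 3.87e-06), 33 (60%, adjusted exact p = 1.25e-06), 30 (57.7%, adjusted exact p = 1.12e-05) and 47 (48.0%, adjusted exact p = 3.55e-05) of the same lists. Examples with both proteins are the polymerase gene Pole (2563 bp for Jmjd2a, 2684 bp for Jmjd2c), the mitotic kinase genes Plk1 (1848 and 2500 bp) and Aurka (630 and 2431 bp), and the helicase subunit gene Mcm4 with Prkdc, a repair kinase gene, at a shared promoter (712 and 2714 bp). Atm and Xrcc6 of the damage response, Srek1ip1, Prpf38a, Prpf38b and Srsf1 of splicing, Psma7, Psmc5, Psmg2 and Psme3ip1 of the proteasome list, and Ndufaf3, Ndufaf5, Cox5a and Atp5j of the mitochondrial list also had both. Zinc finger genes of the Zfp series had Jmjd2a at 260 of 469 (55.4%, 50.8 to 60; adjusted exact p = 3.34e-37) and Jmjd2c at 351 of 469 (74.8%, 70.7 to 78.7; adjusted exact p = 1.84e-59), Zbtb14, Patz1, Zfp516 and Zfp703 having the widest peaks with both proteins.

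Apoptosis regulators and ribosomal protein genes exceeded other genes for Jmjd2c but not for Jmjd2a. Jmjd2c was at 26 of 34 apoptosis genes (76.5%, 58.8 to 89.3; adjusted exact p = 1.42e-05) and Jmjd2a at 10 of 34 (29.4%, adjusted exact p = 0.905). The pro-apoptotic genes Bcl2l11 (1637 bp for Jmjd2a, 2963 bp for Jmjd2c) and Apaf1 (1250 and 1785 bp) and the anti-apoptotic genes Bcl2 (515 and 1790 bp) and Bcl2l1 (347 and 1778 bp) had both. Ribosomal protein genes had Jmjd2c at 44 of 87 (50.6%, 39.6 to 61.5; adjusted exact p = 0.0267) and Jmjd2a at 22 of 87 (25.3%, adjusted exact p = 0.781), with both at Rpl7, Rpl35, Rps13 and Rps21. The Jmjd2c call for ribosomal genes ended against protein-coding genes without predicted genes and receptor families (adjusted exact p = 0.994) and with the wider 50% of peaks (adjusted exact p = 0.161), where the Jmjd2a share was lower than in other genes (adjusted exact p = 0.0218).

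Differentiation genes, markers of other lineages and tissues, histone genes and olfactory and vomeronasal receptor genes mostly had no called peak of either protein. A missing call does not show a missing protein, and how uniquely reads map to these genes was not examined. Of 35 granulocyte and macrophage genes, 4 had Jmjd2a (11.4%, 3.20 to 26.7; adjusted exact p = 0.0453) and 6 had Jmjd2c (17.1%, 6.56 to 33.6; adjusted exact p = 0.0188). Cd14, Cebpd and Klf4 had both, Cebpe had Jmjd2c alone, and Cebpa, named after its values were seen, had Jmjd2a alone. Of 37 lymphoid, erythroid, megakaryocyte and mast cell markers, only the erythroid factor gene Klf1 was occupied, by Jmjd2a (adjusted exact p = 0.000255) and Jmjd2c (adjusted exact p = 2.92e-06). Fibroblast, endothelial and stromal markers had Jmjd2a at 1 of 20 (Lepr, adjusted exact p = 0.0295) and Jmjd2c at 1 of 20 (Pdgfrb, adjusted exact p = 0.00282), and neuronal and muscle genes had Jmjd2a at 1 of 26 (Grin1, adjusted exact p = 0.0056) and Jmjd2c at 1 of 26 (Slc17a7, adjusted exact p = 0.000225). Histone genes had 6 of 86 with Jmjd2a (7.0%, adjusted exact p = 5.99e-06) and 6 of 86 with Jmjd2c (adjusted exact p = 3.15e-10), including H1f0, H2aw, H2az2 and Macroh2a2 with both. None of the 1108 olfactory receptor genes had a called peak of either protein (exact upper bound 0.332%, adjusted exact p = 7.29e-157 for Jmjd2a and 3.38e-234 for Jmjd2c). Vomeronasal receptors had Jmjd2a at 1 of 360 (Vmn2r29, adjusted exact p = 8.47e-48) and Jmjd2c at 0 of 360 (upper bound 1.02%; adjusted exact p = 2.06e-74). The stromal list lost its Jmjd2a call with a 5000 bp window (adjusted exact p = 0.099) and lost both calls with the wider 50% of peaks (adjusted exact p = 0.281 and 0.089).

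**Figure D3:**
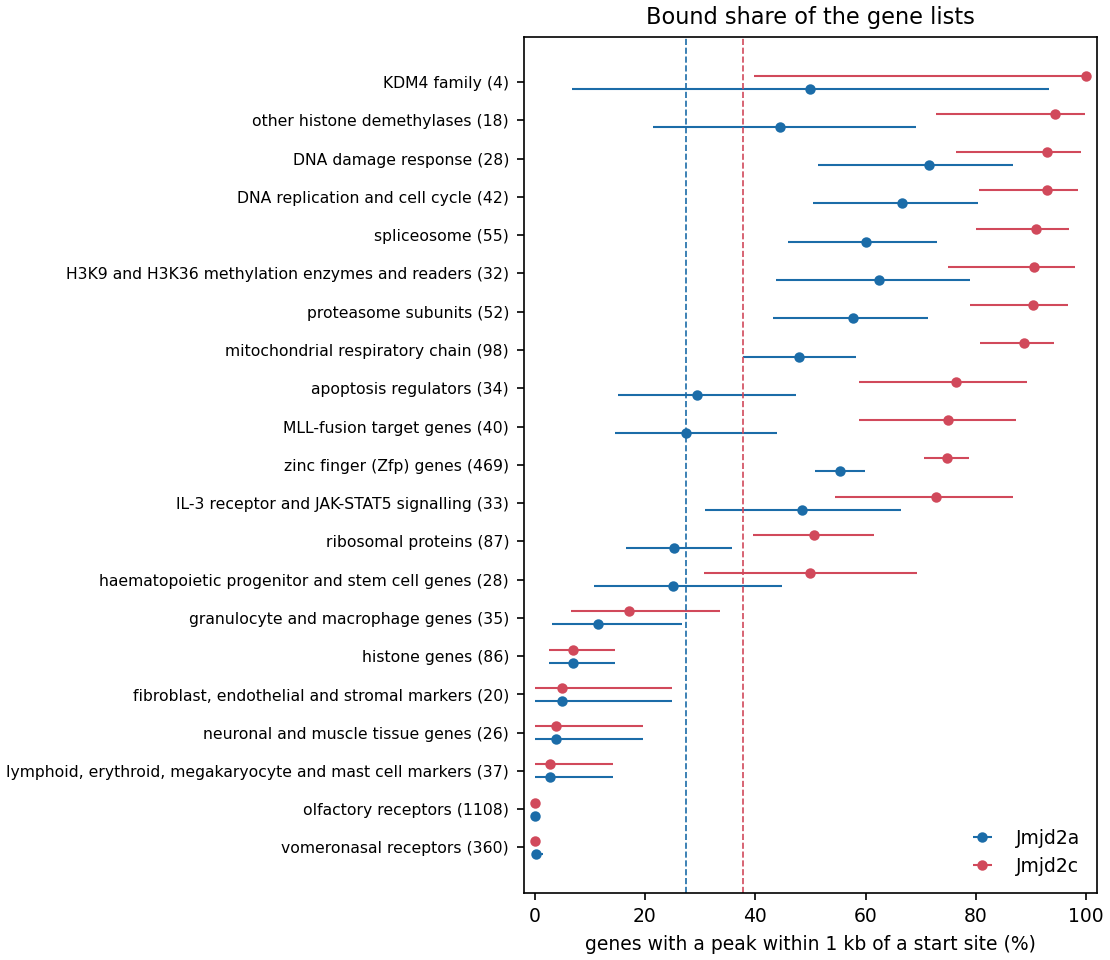
Share of the genes of each list with a Jmjd2a peak (blue) or a Jmjd2c peak (red) within 1 kb of a start site; points are percentages, bars exact 95% binomial intervals, numbers in brackets the genes per list, and dashed lines the shares over all 26219 genes (27.4% and 37.9%). Jmjd2c reaches 100% in the KDM4 family (4 genes) and 94.4% in other histone demethylases (18 genes). No peak of either protein was called at the 1108 olfactory receptor genes.

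A comparison added after the data were seen asked whether Jmjd2a accompanied Jmjd2c evenly across the lists. It did so less often at MLL-fusion targets, at apoptosis regulators and at ribosomal protein genes. Of the Jmjd2c-occupied genes in these lists, Jmjd2a was at 10 of 30 MLL-fusion targets (33.3%, 17.3 to 52.8; adjusted exact p = 0.00725), 8 of 26 apoptosis regulators (30.8%, 14.3 to 51.8; adjusted exact p = 0.00725) and 19 of 44 ribosomal protein genes (43.2%, 28.3 to 59.0; adjusted exact p = 0.0254), against 64.8% of other Jmjd2c genes in each case (Fisher's exact test, 19 lists). Jmjd2c without Jmjd2a was found at Meis1 and Cdk6 among the MLL-fusion targets. No list passed the test with a higher share, the smallest p of that direction being that of the Zfp series, with 247 of 351 (70.4%, adjusted exact p = 0.109). With a 5000 bp window the shares of MLL-fusion targets and ribosomal genes, 43.8% and 47.8% against 66.3%, no longer passed (adjusted exact p = 0.0636 for each). With the wider 50% of peaks the shares stayed below the 43.8% of other genes but rested on fewer genes and did not pass, at 5 of 21 MLL-fusion targets (23.8%, 8.22 to 47.2; odds ratio 0.401 against 0.272, adjusted exact p = 0.352) and 2 of 14 apoptosis regulators (14.3%, 1.78 to 42.8; odds ratio 0.214 against 0.242, adjusted exact p = 0.237).

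X-linked start sites carried less Jmjd2a than autosomal ones, in another comparison added after the data were seen. Jmjd2a overlapped 83 of 275 X-linked Jmjd2c peaks near a start site (30.2%, 24.8 to 36) and 5492 of 8774 autosomal ones (62.6%; odds ratio 0.258, Fisher's exact test, two-sided p = 1.04e-26). The autosomes ranged from 52.6% on chromosome 19 to 71.4% on chromosome 16. Among protein-coding genes, again without predicted genes and receptor families, Jmjd2a occupied 12.1% on the X chromosome against 37.2% on autosomes (odds ratio 0.233, Fisher's exact p = 4.77e-54), and Jmjd2c 33.4% against 50.7% (odds ratio 0.488, exact p = 1.5e-21). X-linked Jmjd2c peaks near start sites were also narrower, with a median of 1129 bp against 1375 bp.

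**Figure D4:**
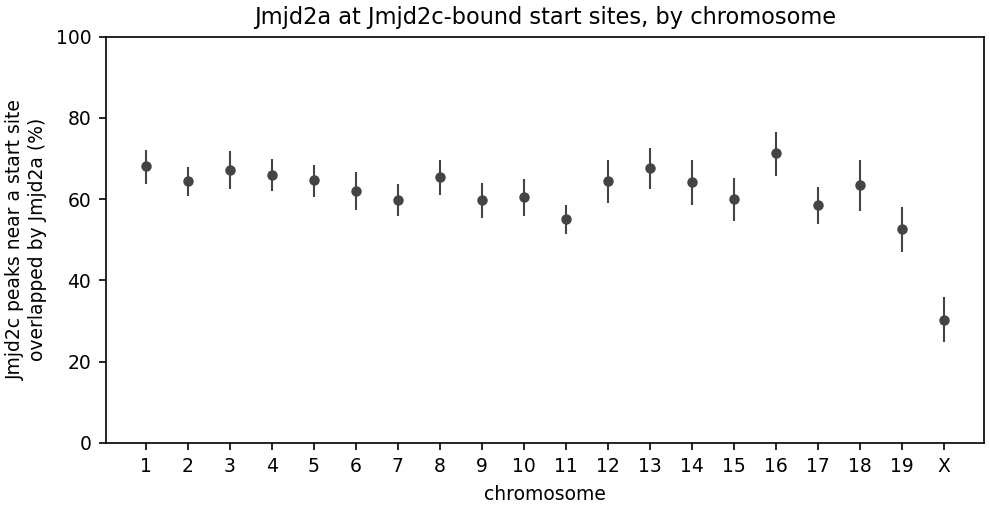
Share of Jmjd2c peaks within 1 kb of a start site that overlap a Jmjd2a peak, for each autosome and the X chromosome; points are percentages and bars exact 95% binomial intervals, which cover counting error only. The X chromosome stands at 30.2%, below the lowest autosome at 52.6%.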

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

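The X-linked and list comparisons were chosen after the data were seen, and so were the tests of peak width and copy number on the X chromosome, the count of peaks on the Y chromosome and the bound for X-linked members of the lists.

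Jmjd2a overlapped 30.2% of X-linked Jmjd2c peaks near start sites, against 62.6% of autosomal ones, a difference of 32.4 percentage points between chromosome classes that passed a direct test. The narrower Jmjd2c peaks on the X chromosome do not account for the whole of it, because at matched width (10 classes) 58.2% would be overlapped, which leaves -28.0 percentage points (permutation p = 0.0001, the smallest that 10000 permutations can give, 275 peaks). A single X copy per cell may lower the signal of both antibodies; it needs fewer Jmjd2c genes on the X chromosome too, and the odds ratio there was 0.488 (Fisher's exact test, p = 1.5e-21). All 4 Jmjd2c peaks and 2 of the 4 Jmjd2a peaks on the Y chromosome lay near start sites, so cells with a Y chromosome were present, although whether every cell line carried one is not given in the sources used here. Fewer Jmjd2c genes would also follow from the makeup of X-linked genes, and no biological explanation was tested.

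Of the gene lists, 3 differed from other Jmjd2c-occupied genes in how often Jmjd2a was present, with 33.3% of MLL-fusion targets, 30.8% of apoptosis regulators and 43.2% of ribosomal protein genes against 64.8%. Their Jmjd2c peaks were not generally narrower, with medians of 1828.5, 1351 and 1474.5 bp for the lists in turn against 1428 bp in other genes, so peak width is no explanation for MLL-fusion targets and ribosomal protein genes. At matched width of the Jmjd2c peak the 99 genes would reach 63.1% in place of 36.4%. This is a difference of -26.8 percentage points (permutation p = 0.0001, the smallest that 10000 permutations can give). For the lists in turn the difference was -30.8, -33.9 and -18.1 points. The lists were picked for a low Jmjd2a share in these same data, so this p adds no independent evidence of the gap. The matching shows only that peak width does not remove the gap. X-linked members number 3 of the 99, too few to produce the gap: without them the share was 36.5% of 96 genes, and if all 3 had carried Jmjd2a it would be 38.4%. A weaker Jmjd2a signal below an unknown calling threshold stays open, and no biological explanation was tested.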

How the results depend on the processing

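The settings with the wider 50% of peaks, 500 bp peaks, added gene ends and no X-linked genes, and all settings of the X-linked comparison and of Jmjd2a among Jmjd2c genes, were chosen after the data were seen. No direction that passed a test reversed under any setting run, the Jmjd2c excess near start sites kept its side of the threshold at 7.84 to 10.8 percentage points, and the X-linked deficit stood at -29.8 with 500 bp peaks and -27.0 with the wider peaks. The share near start sites for Jmjd2a and Jmjd2c moved to 74.1% and 84.9% with a 500 bp window, to 81.4% and 89.3% with a 5000 bp window, and to 86.0% and 94.9% among the wider 50% of peaks (4499 and 5267 peaks). Shared Jmjd2a peaks fell to 73.0% when 50% of the shorter peak had to overlap. Shared Jmjd2a and Jmjd2c peaks came to 76.3% and 60.8% within 1000 bp of each other, 52.5% and 43.9% among the wider peaks and 64.6% and 53.7% for 500 bp peaks. The wider setting removes partners from both lists, and the cause was not tested for the other 2. The wider peaks also left 2622 genes with both proteins and 3 lists with a lower share of such genes in place of 7; fewer peaks were tested. Lists with less Jmjd2a among Jmjd2c genes went from 3 to 1 with the 5000 bp window (apoptosis regulators, where the cause was not tested) and to 1 with the wider peaks (ribosomal proteins, fewer genes tested). Over the list tests, 139 of the Jmjd2a, 140 of the Jmjd2c and 137 of the joint results under 7 alternatives stayed on the same side of the threshold, while 5, 6 and 7 fell below it and 2, 0 and 2 rose above it. The losses of each set include the vomeronasal list against the background without receptor families, which itself removes all but 2 of its 360 genes. The olfactory list kept no gene in that background and was not counted there. Over the alternatives the adjusted exact p ran from 0.00909 to 0.827 for Jmjd2a at interleukin-3 signalling genes, from 0.0256 to 0.089 for Jmjd2c at the KDM4 family, from 0.0109 to 0.994 for Jmjd2c and 0.0218 to 1 for Jmjd2a at ribosomal protein genes, from 0.023 to 0.568 for Jmjd2a and 0.0155 to 0.413 for both proteins at other histone demethylases, and from 0.00359 to 0.281 for Jmjd2a and 0.000132 to 0.089 for Jmjd2c at stromal markers. Among Jmjd2c genes it ran from 0.00763 to 0.352 for MLL-fusion targets, 0.00763 to 0.237 for apoptosis regulators and 0.026 to 0.0636 for ribosomal proteins. No paired analysis was possible because no column used here carries values per library, although the histone mark groups share replicate numbers. For the same reason the OHT settings were not run, nor were a score threshold, reference start sites or matching on CpG-rich promoters, which need a score, strands or a genome sequence. Unknown depth limits every absent peak: it means not called, not unoccupied.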

Other observations

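All regions in the next paragraph were chosen after their values were seen; the tests that follow it were written before their results.

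The Hoxa cluster, whose genes are a hallmark of MLL-rearranged leukaemia, held 9 Jmjd2c peaks and 2 Jmjd2a peaks over its genes and 10 kb on each side (chromosome 6, 52145367 to 52270880). Jmjd2c peaks without Jmjd2a covered start sites of Hoxa3 (1624 bp), Hoxa4 (431 bp), Hoxa10 (2902 bp), Hoxa11 (2152 bp) and the microRNA gene Mir196b (1321 bp). The Hoxb, Hoxc and Hoxd clusters, with the same flanks, held 4, 1 and 1 Jmjd2c peaks and 2, 1 and 3 Jmjd2a peaks. Meis1 had Jmjd2c peaks 143, 1512 and 7030 bp from its start, and the farthest (1842 bp; chromosome 11, 19025999 to 19027840) overlapped the locus's Jmjd2a peak of 1527 bp. None of these differences between clusters was tested.

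At start sites of peak pairs that match each other alone, Jmjd2a peaks covered the start site in 73.8% and Jmjd2c peaks in 95.2% of 5080 pairs. Narrower Jmjd2a peaks may account for part of this gap: intervals as wide as the Jmjd2a peak, centred on the Jmjd2c peak, covered it in 82.5%, which leaves -8.72 percentage points (exact binomial test of discordant pairs, p = 6.52e-41). Centring on the Jmjd2c peak is an assumption, the remainder lies between the bounds set beforehand, and its source was not tested. No biological explanation was tested.

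A hypothesis was that promoters serving genes on both strands carry Jmjd2a more often. The 1876 Jmjd2c peaks near start sites with features on both strands overlapped Jmjd2a in 60.1%, against 63.4% at matched width. The difference of -3.29 percentage points (permutation p = 0.0051) is opposite in direction to the hypothesis. These features need not be start sites, so the test does not bear directly on promoters serving genes on both strands.

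Another hypothesis was that reads shared with processed pseudogenes could lower peak calls at ribosomal protein genes. The 43 genes without a Jmjd2c peak had 3.42 named pseudogenes on average and the 44 with a peak 3.86, a difference of -0.445 (permutation p = 0.684). Beforehand, a mean no higher in genes without a peak was set to count against the hypothesis, with no condition on p. Because the difference lies within the permutation spread, the hypothesis was afterwards left open. This test does not bear on Jmjd2a at genes that carry Jmjd2c.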
